A study of Mus musculus with 6 samples.

How the data were processed

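The samples are bladder neck and urethra of FVB/N mouse embryos at embryonic day 13, separated into epithelium (arrays 1, 2 and 5) and mesenchyme (arrays 1, 2 and 3), the numbers being those of the sample titles. Per the labels' protocols, the tissue was digested with trypsin, the layers were parted with a needle, and total RNA was purified on columns, amplified in 2 rounds and biotin-labelled for the Affymetrix mouse whole-genome expression array. Samples were not pooled and sex is unknown, per the labels. The labels' texts differ on whether the bladder was cut above, below or at the level of the ureters.

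The deposited table holds 1 probe set intensity (signal) per array on a linear scale. GCOS, the Affymetrix software, is named per the submitters' processing notes, and its version and settings are not given in the sources used here. Measured on the deposited table, each array's mean intensity without its top and bottom 2% of probe sets was 1500, so the authors' values carry a common scaling. The table used here carries no detection calls, so probe sets near background have no bound and their fold changes are on the log2(signal + 16) scale, which understates the change of dim genes. Array medians lay between 126 and 254, a ratio of 2.02, just over the 2-fold limit set before the data were examined, so values were quantile normalized after log2(signal + 16). The number of arrays, 3 per layer, limits the precision of every value.

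Of 45101 probe sets, 64 are controls and were left out. By the platform annotation, 34945 of the others name 1 gene, 932 several and 9160 are unnamed here. Of 34958 single-gene entries, 34754 were matched by gene identifier to the RefSeq table of assembly GRCm38.p6, which changed 0 symbols. The array table names no build, so no coordinates are given. Probe sets whose mean log2 value over all arrays exceeded the 40th percentile were kept, and each gene was represented by its probe set of highest mean over all 6 arrays, which left 13717 of 18194 genes. Of 5900 genes with several tested probe sets, 0 had probe sets called in opposite directions. Such a case needs both probe sets past the threshold, so this count does not show that the probe sets of a gene agreed. Of 3557 tested probe sets without a single gene name, 57 passed the threshold, and they are not named. Probe sets whose names end in _x_at, _s_at or _a_at can match several transcripts, of the same or of related genes. Among named genes, Tgfbi, Sox17, Hbb-y, Slc4a1 and Rrm2 are read from _x_at sets, Fgfr2, Smo and Xist from _s_at sets, and Actg2, Adgre1, Aplnr, Cldn3, Epha2, Krt7, Krt8, Krt10, Lama3, Nid2, Tnnt1 and Tpm2 from _a_at sets.

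Epithelium and mesenchyme were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, all 6 arrays, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. No covariate was used because no label says that a shared number marks the same embryo. Fixed before the data were examined were 29 gene lists and 56 ligand and receptor pairs. The 28 lists other than the sex-linked genes were tested with camera at a preset correlation of 0.01, with the correlation estimated, and with fry, each adjusted over the 28 lists. Counts are given over all genes and adjusted over the list alone. Of the pairs, 46 had both members tested and were compared with 100000 seeded re-pairings of the same ligands and receptors.

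Named genes are the 12 with the largest difference in each direction among genes past the threshold whose arrays did not overlap between layers and whose probe set is not of the cross-matching _x_at kind, up to 4 members of each list with the largest difference past the threshold, the 2 brightest members as values where fewer than 2 passed, both members of pairs across the layers, and Shh, Fgf10, Fgf7, Wnt4, Wnt5a and Bmp4 whatever their result. Boc, Rspo3, Fos, Junb, Hspb1, Hspa1a, Hspa1b, Hoxd13, Hoxa10, Isl1, Tbx3, Kdm5d, Uty and the organ markers were named after values of the arrays had been seen.

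The code was tested on simulated data with each gene's spread as moderated by limma and 200 changed genes. The simulated noise was independent between genes and of equal spread on all arrays. On the real arrays mesenchyme 1 shifted many genes together, so the shares below may not hold for them. With all 6 arrays and 13717 genes, 4% of genes changed by 1 log2 unit were recovered, 38% at 2, 82% at 3 and 90% at 4, with 7 unchanged genes called. Without mesenchyme 1 and with 13587 genes these shares were 16%, 74%, 90% and 98%, with 9 unchanged genes called.

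Alternatives fixed in advance were other offsets, no normalization, median centring, no filter or a filter at the 60th percentile, the mean of a gene's probe sets, all probe sets, only probe sets of the unique kind, eBayes without a trend or robust, array quality weights, a test of each gene on its own variance, the replicate number as a block, and each array left out in turn. Added after seeing the data were the list and pair counts without mesenchyme 1, and that array left out together with no normalization. The block and the check of whether numbers pair the arrays are reported in the closing section.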

Results

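Gene expression was measured in the epithelium and the surrounding mesenchyme of the developing bladder neck and urethra of wild-type FVB/N mouse embryos at embryonic day 13 (Theiler stage 21). The question set by the labels is which genes distinguish the 2 tissue layers, which were peeled apart after trypsin treatment. Each layer was hybridised to 3 Affymetrix mouse whole-genome expression arrays, numbered 1, 2 and 5 for epithelium and 1, 2 and 3 for mesenchyme. Array medians of the deposited signal ran from 126 on epithelium 2 to 254 on mesenchyme 1, and the number of arrays limits the precision of every value. Fold changes below are log2 differences, epithelium minus mesenchyme, of quantile-normalized log2(signal + 16), with the standard error from limma (n = 3 arrays per layer), so a positive value is higher in epithelium. The labels do not say whether each array came from its own embryo, so limma's p-values of single genes measure the spread between these samples. That spread may be technical. Camera at the preset correlation compares a list's genes with the other genes, so its small p-values do not measure that spread. Nor do the p-values of Fisher's exact test on gene families and of re-pairing.

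The array labelled mesenchyme 1 stood apart from mesenchyme 2 and 3, so counts of genes past the threshold over all genes are also given without it. Across genes, which are not independent replicates, mesenchyme 2 and 3 correlated at r = 0.981 and the epithelial arrays at 0.922 to 0.958, while mesenchyme 1 correlated at 0.784 and 0.755 with mesenchyme 2 and 3. The liver transcripts Alb (albumin) and Ttr (transthyretin) read 58365 and 59268 normalized signal units on mesenchyme 1, where Alb read 100.3 to 216 and Ttr 4.3 to 85.0 on the other arrays. Cardiac Myh6 read 10143 there and at most 124 elsewhere, the pancreatic enzyme Cpb1 33800 and at most 312, the lung surfactant gene Sftpc 26025 and at most 265, and epidermal Flg 12314 and at most 25.7. Hoxd13, a homeobox gene of the caudal body, read 504 on mesenchyme 1 and 31870 to 42463 on the other 5 arrays, and the transcription factor Isl1 read 978 against 21092 to 27174. Xist, transcribed from the inactive X chromosome, read 28082 on mesenchyme 1, 17019 on mesenchyme 3 and 385 to 592 on the others, and Y-linked Eif2s3y read 1542 on mesenchyme 1, 175 on mesenchyme 3 and 3072 to 5133 on the others. Of 49 organ markers, 27 lay over 4-fold above the highest of the other 5 arrays on mesenchyme 1 and 22 did not, some of them lower there, such as Gfap (138) of glia and Gad1 (22.0) of inhibitory neurons. The 49 were chosen after this array was seen to differ, before their own values were looked at, while those named here and Hoxd13 and Isl1 were chosen after their values were seen.

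**Figure D1:**
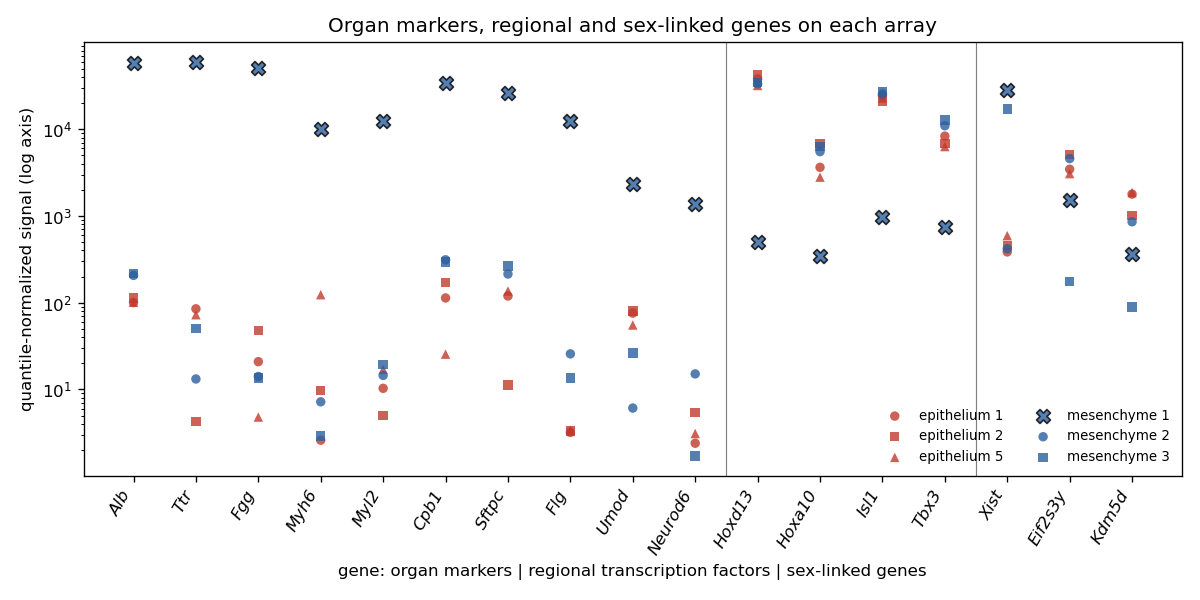
Quantile-normalized signal on a log axis of 10 organ markers, picked from the 27 of 49 that lay over 4-fold above the other arrays, 4 regional transcription factors and 3 sex-linked genes, with a point per array (red epithelium, blue mesenchyme, outlined cross mesenchyme 1). By that choice mesenchyme 1 lies above the other 5 arrays for the organ markers drawn (Alb 58365), and it lies below them for Hoxd13 (504), Hoxa10 (343), Isl1 (978) and Tbx3 (742).

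With all 6 arrays, most of the 12 genes with the largest excess in epithelium encode transcription factors, with a pair of claudins beside them. Hoxd1, a homeobox gene, was 63.2-fold higher (log2 5.98 ± 0.771 SE, adjusted p = 0.00803), and Elf5, an ETS factor of glandular epithelia, 59.6-fold higher (log2 5.90 ± 0.967, adjusted p = 0.0162). Without mesenchyme 1 these folds were 35.8 for Hoxd1 and 126 for Elf5. The pioneer factor Foxa1 (4.84), the grainyhead factors Grhl2 (4.83) and Grhl3 (4.65), the zinc finger genes Sp8 (5.14) and Zfp750 (4.73) and the caudal Hox gene Hoxb13 (4.65) followed. Of the rest, Cldn23 (5.60) and Cldn3 (4.57) encode tight junction claudins, Upk3bl (5.01) a relative of the uroplakins and Prss22 (4.62) a serine protease. Adjusted p of these 12 genes lay between 0.00358 for Grhl3 and 0.0413 for Cldn3 in limma, and Cldn3 missed the threshold without the filter (adjusted p = 0.0534) and without a variance trend (adjusted p = 0.0588). The make-up of the 12 depended on mesenchyme 1. Without that array the 12 largest were led by Pkp1 and Krt15, and only Elf5 and Cldn23 stood in both sets.

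Among the 12 genes with the largest excess in mesenchyme were a vascular receptor, neuronal genes, extracellular regulators and a muscle gene. Aplnr, the apelin receptor of endothelium, differed by -8.14 ± 0.790 SE on the log2 scale (283-fold, adjusted p = 0.00394), and Rgs4, a regulator of G-protein signalling, by -7.94 ± 0.406 (adjusted p = 0.00146). Bmper, a secreted BMP-binding protein, differed by -7.06, and the angiotensin II receptor Agtr2 by -6.41. The neuronal genes Stmn2 (-6.79), Snap25 (-6.37) and Prph (-6.28) were in this group, as were Rab6b (-5.94), the matricellular gene Sparcl1 (-6.09), the peptidase Enpep (-5.72) and the slow muscle troponin Tnnt1 (-5.85). Pnliprp1, a lipase relative known from pancreas, read 25040 on mesenchyme 1, 4886 and 4364 on mesenchyme 2 and 3 and at most 147 on the epithelial arrays (-6.07). The sizes and their order depended on the probe sets: with the mean of a gene's probe sets Aplnr was at -6.51, Rgs4 at -4.37, Stmn2 at -4.60, Prph at -3.41, Rab6b at -4.72 and Grhl2 at 3.53, all still past the threshold, and Aplnr was at -4.88 without probe sets that can match several transcripts. With an offset of 1, Rgs4 (-9.15) lay below Aplnr (-8.84). All 24 of these genes kept adjusted p under 0.05 without mesenchyme 1, from 0.000607 for Rgs4 to 0.0114 for Sparcl1. They were chosen as past the threshold with that outlying array included, and genes past it rose from 820 to 1975 without the array. Keeping the call there is therefore weak support. Leaving out another array ended the call of 9 of the 24 (epithelium 1), 6 (epithelium 2), 8 (epithelium 5), 7 (mesenchyme 2) or 4 (mesenchyme 3), with Prph, Cldn3 and Zfp750 among them each time and Elf5, Foxa1, Cldn23, Sparcl1, Hoxd1 and Hoxb13 in some.

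**Figure D2:**
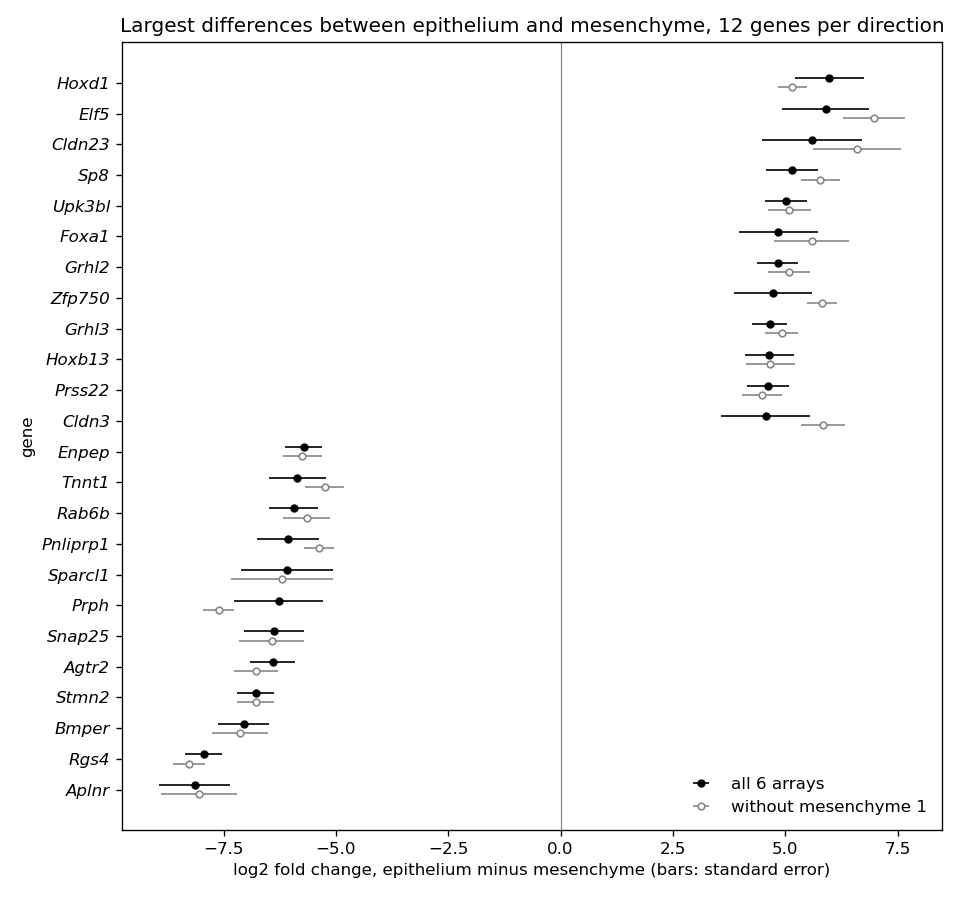
Log2 fold change, epithelium minus mesenchyme, of the 12 genes with the largest difference in each direction, with standard errors, from all 6 arrays (filled) and without mesenchyme 1 (open). With all arrays the values run from -8.14 for Aplnr to 5.98 for Hoxd1, without mesenchyme 1 from -8.27 for Rgs4 to 6.98 for Elf5, and no gene drawn changes sign.

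In all, 820 of 13717 tested genes passed adjusted p 0.05 in limma, 267 higher in epithelium and 553 higher in mesenchyme, and 803 of them differed at least 2-fold (257 and 546; 1851 without mesenchyme 1). At an unadjusted p under 0.05 there were 2670 genes (3582 without mesenchyme 1), and the 3 arrays of 1 layer all lay above those of the other for 3944 genes (28.8% of those tested, where chance gives 10%). Without mesenchyme 1, 1975 of 13587 genes passed, 865 higher in epithelium and 1110 in mesenchyme, and 801 of the 820 were again past the threshold in the same direction. The median log2 difference over all tested genes was 0.12, against 0.06 without normalization and 0.23 with median centring, and the changes given here do not subtract it. Leaving out any of the 6 arrays moved at least 1 of these counts by more than 1.5 times, from 142 genes without epithelium 1 to 1975 without mesenchyme 1. Of the 84 genes past the threshold that are named by rule, 51 lost their call without epithelium 1, 22 without epithelium 2, 42 without epithelium 5, 46 without mesenchyme 2, 30 without mesenchyme 3 and 0 without mesenchyme 1. The 820 and the 84 were chosen with mesenchyme 1 included, so the calls kept without it are weak support for them. The fold of 15 of the 84 was over 1.5 times larger without mesenchyme 1, as for Tbx4 (28.9 to 62.5), Cldn3 (23.7 to 57.3) and Lama3 (13.7 to 27.6), and of 6 over 1.5 times smaller, as for Myh3 (42.1 to 22.4).

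Of 32 epithelial junction and adhesion genes, 9 passed over all genes and 32 adjusted over the list alone, all higher in epithelium, with a median log2 difference of 3.44 (4.48 without mesenchyme 1 and 2.41 without mesenchyme 3). Among them were Cldn3, Marveld2 (3.69 ± 0.763, adjusted p = 0.0532 without a variance trend) and Marveld3 (3.51), tight junction proteins, and Cldn6 (3.67 ± 0.394, adjusted p = 0.00484). Limma's camera with a preset correlation of 0.01 gave adjusted p = 9.96e-16 for the list, and adjusted p = 0.324 with an estimated correlation and 0.0516 by fry. Without mesenchyme 1 all 32 passed over all genes, and mesenchyme 1 itself lay 3.53 log2 units above the mean of mesenchyme 2 and 3 in the list's median, close to the 4.34 to 4.50 of the epithelial arrays.

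Of 14 keratins, the intermediate filament proteins of epithelia, 1 passed over all genes and 6 adjusted over the list alone (median 3.45, adjusted p = 0.000325 with the preset and 0.509 with an estimated correlation), the median being 4.96 without mesenchyme 1 and 2.08 without mesenchyme 3. Krt7, a keratin of simple epithelia, was the member that passed (3.92 ± 0.762, adjusted p = 0.0288). Krt8 had a difference of 3.53 (adjusted p = 0.0987, and 0.0337 with median centring) and Krt10, the keratin of upper epidermis, of 0.01 (adjusted p = 0.998). Krt10 read 74373 on mesenchyme 1 and 1604 to 10051 on the other arrays. Without mesenchyme 1, 11 of 13 keratins passed, all higher in epithelium.

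Among urothelial differentiation genes, 3 of 12 were past the threshold and 5 adjusted over the list alone, with a median of 0.42. Those that passed were Upk3bl, Grhl3 and Snx31 (2.56 ± 0.444, adjusted p = 0.0197), a sorting nexin that binds uroplakins. The list reached adjusted p = 0.0371 with the preset and adjusted p = 0.246 with an estimated correlation, and 6 members passed without mesenchyme 1. Its median depended on the filter on low signals, at -0.05 without it and 4.42 (adjusted p = 0.00233) at the 60th percentile, and the set missed the threshold without epithelium 2 (adjusted p = 0.119) or mesenchyme 3 (0.0583).

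Among transcription factors of epithelia, 16 of 23 were higher in epithelium and 22 when adjusted over the list alone (median 3.47, or 4.30 without mesenchyme 1 and 2.72 with the mean of probe sets). The list includes Elf5, Foxa1, Grhl2 and Zfp750 above. Camera gave adjusted p = 5.97e-19 with the preset and adjusted p = 0.201 with an estimated correlation, and all 23 passed without mesenchyme 1. On mesenchyme 1 these factors lay 1.31 log2 units above mesenchyme 2 and 3, less than the junction genes and the keratins (4.60) did.

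Of 33 fibrous matrix genes, 18 were higher in mesenchyme and 0 in epithelium (27 adjusted over the list alone, median -2.46). Ogn, the small proteoglycan osteoglycin, differed by -5.19 ± 0.491 (36.5-fold, adjusted p = 0.0039), the elastic fibre protein Mfap4 by -4.04, the fibril-associated collagen Col12a1 by -3.95 (-2.13 with the mean of probe sets) and the collagen cross-linking enzyme Lox by -3.83. The list had adjusted p = 7.34e-24 with the preset and adjusted p = 0.0602 with an estimated correlation, and 24 passed without mesenchyme 1.

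Mesenchymal transcription factors showed 9 of 35 genes higher in mesenchyme (12 adjusted over the list alone, with 1 in the other direction, median -1.35, or -2.06 without mesenchyme 1). The T-box genes Tbx4 (-4.85) and Tbx20 (-4.84 ± 0.569, adjusted p = 0.00599), Ebf3 (-3.86) and Zeb2 (-3.56), a repressor of epithelial genes, were among them, and Zeb2 missed the threshold with the mean of probe sets (-2.13, adjusted p = 0.0584). Adjusted p was 1.03e-06 with the preset and 0.47 with an estimated correlation. Without mesenchyme 1, 21 were higher in mesenchyme and 1 in epithelium. The list's median on that array was -1.29 relative to mesenchyme 2 and 3.

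Smooth muscle genes had 6 of 20 members higher in mesenchyme (9 adjusted over the list alone, median -1.55), among them the enteric actin Actg2 (-3.89 ± 0.669, adjusted p = 0.0191), the myosin light chain kinase Mylk (-2.63), Myl9 (-2.43) and Tpm2 (-2.82). Tpm2 read 0.01 on the probe set left when those that can match several transcripts were set aside. Camera gave adjusted p = 3.67e-08 with the preset and adjusted p = 0.0602 with an estimated correlation, and 9 of 19 passed without mesenchyme 1.

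Basement membrane genes split between the layers, with 5 higher in epithelium and 6 higher in mesenchyme of 27 tested (12 and 6 adjusted over the list alone, median 0.75). Lama3, the laminin alpha chain of epithelial basement membranes, was higher in epithelium (3.77 ± 0.754, adjusted p = 0.0317), whereas Lama4 (-5.03 ± 0.712, adjusted p = 0.0105), Nid2 (-4.06) and Lama2 (-3.26) were higher in mesenchyme. As a set they did not pass in camera (adjusted p = 0.121, and adjusted p = 0.324 with an estimated correlation), and did by fry (0.0124). Without mesenchyme 1 the counts were 12 and 6 of 26 and the set passed with the preset (adjusted p = 0.0274) but not with an estimated correlation (adjusted p = 0.164).

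**Figure D3:**
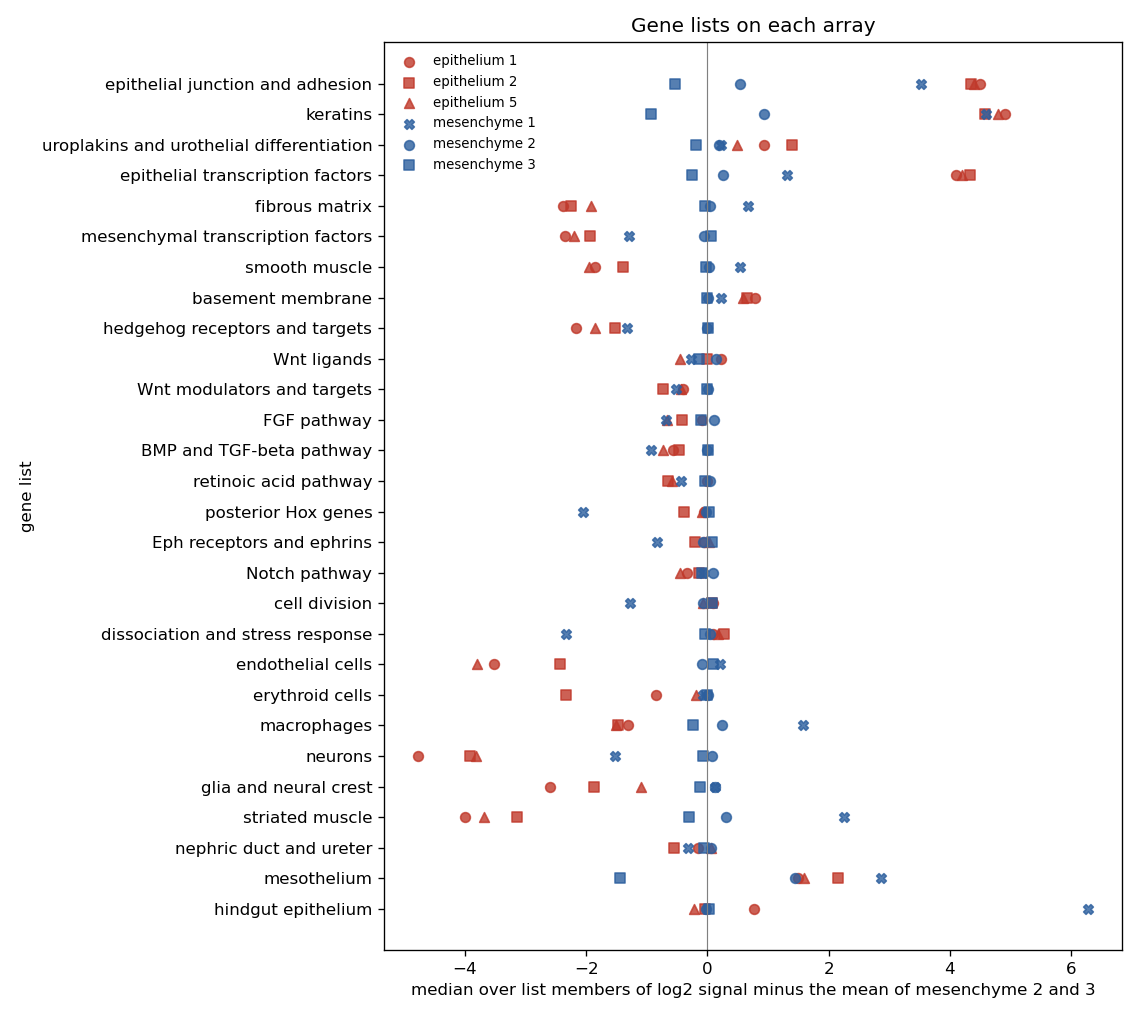
Median over each gene list of log2 signal minus the mean of mesenchyme 2 and 3, with a point per array (red epithelium, blue mesenchyme, cross mesenchyme 1). The epithelial arrays lie at 4.34 to 4.50 for junction genes and at -4.78 to -3.82 for neurons, and mesenchyme 1 lies at 3.53 for junction genes, 6.29 for hindgut genes and -2.33 for stress genes. Of 11 hindgut genes, 5 passed the signal filter with all arrays and 2 without mesenchyme 1, so the hindgut value is partly set by the filter.

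Of the 6 ligands named in advance, none passed in limma over all 6 arrays as processed here, and 3 passed without mesenchyme 1. Shh, the hedgehog ligand, read 49306 to 50758 on the epithelial arrays and 9283, 6259 and 191 on mesenchyme 1, 2 and 3, a difference of 4.45 ± 1.31 (adjusted p = 0.108) that became 5.50 (adjusted p = 0.0266) without mesenchyme 1. Wnt4 had a difference of 3.71 (adjusted p = 0.0558, and 0.00438 without mesenchyme 1), which passed over all 6 arrays with median centring (0.0218), the mean of probe sets (0.0241), no normalization (0.0476) and the filter at the 60th percentile (0.0485), and Bmp4 of -1.04 (adjusted p = 0.615), or -2.40 (adjusted p = 0.002) without mesenchyme 1, where it read 409 against 6513 and 6508. Fgf7 (-2.49, adjusted p = 0.175), Fgf10 (-1.26, adjusted p = 0.273) and Wnt5a (-0.76, adjusted p = 0.418) did not pass in either fit. Array quality weights, whose estimate stopped early, brought all but Fgf7 past the threshold.

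Hedgehog receptors and targets had 1 of 12 members past the threshold (2 adjusted over the list alone, median -1.12, or -2.27 without mesenchyme 1 and -0.45 without mesenchyme 3). Gas1, a hedgehog co-receptor, was higher in mesenchyme (-2.62 ± 0.297, adjusted p = 0.00579), a call that ended with the mean of its probe sets (-1.37, adjusted p = 0.189), while the receptor Ptch1 and the transducer Smo had differences of -0.27 and 0.43. The list reached adjusted p = 0.00353 with the preset and adjusted p = 0.478 with an estimated correlation, and 6 members passed without mesenchyme 1.

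Wnt genes went both ways. Among 12 Wnt ligands, 3 were higher in epithelium, including Wnt6 (3.12 ± 0.451, adjusted p = 0.0112) and Wnt10a (3.04), and 2 in mesenchyme, Wnt2 (-4.17 ± 0.690, adjusted p = 0.0164) and Wnt9a (-2.57); adjusted over the list alone the counts were 5 and 2. Of 23 Wnt modulators and targets, the receptor-removing ligase Rnf43 (3.81) and the R-spondin receptor Lgr4 (1.39) were higher in epithelium, and the ligand Rspo2 (-4.25 ± 0.825, adjusted p = 0.0288) and the inhibitor Dkk1 (-1.94) in mesenchyme, with 5 and 4 adjusted over the list alone. Lgr4 and Dkk1 missed the threshold with median centring (adjusted p = 0.138 and 0.0507) and without the filter (0.0529 and 0.0534), and Lgr4 also without a variance trend (0.0723). Neither list passed as a set (adjusted p = 0.617 and 0.47, and adjusted p = 0.744 and 0.644 with an estimated correlation). Without mesenchyme 1 the counts were 4 and 3 of 15 ligands, whose median (-0.13) and mean (0.32) differed in sign, and 6 and 7 of 23 modulators.

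Of 16 FGF pathway genes, the receptors Fgfr3 (3.20 ± 0.712, adjusted p = 0.0449) and Fgfr2 (1.31 ± 0.204, adjusted p = 0.0139) were higher in epithelium, with 4 and 4 in each direction adjusted over the list alone, and 2 and 4 over all genes without mesenchyme 1. Fgfr2 missed the threshold with median centring (adjusted p = 0.0572), and Fgfr3 without the filter (0.0555) or a variance trend (0.0652). The set did not pass (adjusted p = 0.691, and 0.832 with an estimated correlation). BMP and TGF-beta genes had 4 of 28 higher in mesenchyme (6 adjusted over the list alone, median -0.46). These were the ligands Tgfb3 (-3.37 ± 0.289, adjusted p = 0.00358) and Inhba (-2.87), the matrix protein Tgfbi (-2.67) and the receptor Tgfbr2 (-2.08, adjusted p = 0.0562 with median centring). Adjusted p was 0.00407 with the preset and 0.478 with an estimated correlation, and 9 passed without mesenchyme 1.

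No retinoic acid pathway gene passed among 15, with 6 at an unadjusted p under 0.05 in limma and 0 adjusted over the list alone. The members with the brightest probe sets were the receptor Rxrb (0.21) and the retinol dehydrogenase Rdh10, at -1.40 (adjusted p = 0.281), or -2.14 (adjusted p = 0.00548) without mesenchyme 1. The set test gave adjusted p = 0.617 and, with an estimated correlation, 0.744. Without mesenchyme 1, 1 of 16 was higher in epithelium and 5 in mesenchyme.

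Eph receptors and ephrins included Epha1 (3.20 ± 0.546, adjusted p = 0.0188) and Epha2 (2.26) higher in epithelium, and Ephb1 (-2.46) and Epha5 (-2.12 ± 0.371, adjusted p = 0.0201) higher in mesenchyme, of 18 tested (3 and 2 adjusted over the list alone). In the Notch pathway, the target Hes1 was higher in epithelium (3.08 ± 0.299, adjusted p = 0.00394), and Mfng (-3.85), Notch4 (-2.88) and Hey1 (-1.39) in mesenchyme, of 16 tested (3 and 4 adjusted over the list alone). Several of these calls depended on the setting. With an offset of 1 Epha1 was at 1.23 (adjusted p = 0.221), with the mean of probe sets Epha5 was at -2.08 (0.101) and Notch4 at -1.12 (0.372), without the filter Ephb1 (0.0577), Notch4 (0.057) and Hey1 (0.0503) missed the threshold, without a variance trend Ephb1 (0.0523) did, and with median centring Hey1 (0.225) did. Neither set passed (adjusted p = 0.691 and 0.356, and adjusted p = 0.832 and 0.644 with an estimated correlation). Without mesenchyme 1, 3 and 6 Eph genes and 2 and 3 Notch genes passed.

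Among 12 posterior Hox genes, which mark caudal position, Hoxb13 and Hoxa9 (1.38 ± 0.213, adjusted p = 0.0135) were higher in epithelium, also when adjusted over the list alone, though Hoxa9 missed the threshold with median centring (adjusted p = 0.0701). The median was 0.73 over all arrays and -0.26 without mesenchyme 1, where the mean was 0.16 and 2 and 1 genes passed, and mesenchyme 1 lay at -2.05 against the other mesenchyme arrays. The set did not pass (adjusted p = 0.109, and 0.692 with an estimated correlation), but did with all probe sets (0.0368) and without mesenchyme 2 (0.0184) or 3 (0.0152).

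Of 27 cell division genes, 0 passed in limma over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05. Pcna and Rrm2, of DNA replication, had differences of 0.08 and -0.28. Camera gave adjusted p = 0.0407 with the preset (median 0.48) and adjusted p = 0.744 with an estimated correlation. Without mesenchyme 1, which lay at -1.28 for this list, the median was -0.02, the mean 0.01 and adjusted p = 0.97. The set also missed the threshold with the filter at the 60th percentile (adjusted p = 0.0834), without cross-matching probe sets (0.0716) and without epithelium 1 (0.0666) or 2 (0.125).

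Among immediate-early genes, which tissue dissociation can induce, Fos lay at percentiles 99.5 to 99.8 of all probe sets on the arrays other than mesenchyme 1 and at 93.2 there. Not all members ranked so high: Junb, the lowest, lay at percentiles 52.85 to 62.1 on those arrays and at 14.55 on mesenchyme 1. Egr1 read 50220 to 59822 on the other 5 arrays and 11049 on mesenchyme 1, a difference between layers of 0.69 (adjusted p = 0.573), and the chaperone gene Dnajb1 had one of 0.56. Of 19 immediate-early and heat shock genes, 0 passed over all genes or adjusted over the list alone, and 6 were at an unadjusted p under 0.05 in limma (median 0.92, adjusted p = 0.00267 with the preset and 0.478 with an estimated correlation). Mesenchyme 1 lay at -2.33 for this list, while the heat shock genes Hspb1 (3.91), Hspa1b (2.35) and Hspa1a (1.87) lay above mesenchyme 2 and 3 there, and without it 4 were higher in epithelium and the median was 0.14. With array quality weights the set missed the threshold (median 0.23, adjusted p = 0.0589).

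Among markers of other cell types, endothelial, neuronal, glial and striated muscle lists had genes past the threshold. Of 16 endothelial genes, 9 were higher in mesenchyme (13 adjusted over the list alone, median -3.17), with Plvap (-5.58 ± 0.375, adjusted p = 0.00231), Sox17 (-5.10), Cdh5 (-4.52) and Cldn5 (-4.37) in the lead. The list had adjusted p = 1.53e-13 with the preset and adjusted p = 0.0602 with an estimated correlation, and 12 passed without mesenchyme 1. Of 14 neuronal genes, 9 were higher in mesenchyme (10 adjusted over the list alone, median -3.65), with Gap43 of growing axons at -5.08 ± 0.512 beside Stmn2, Snap25 and Prph. Camera gave adjusted p = 4.76e-11 and, with an estimated correlation, adjusted p = 0.16, and 12 passed without mesenchyme 1. Glial and neural crest genes had 3 of 7 higher in mesenchyme, Fabp7 (-5.09), Ednrb (-3.85 ± 0.286, adjusted p = 0.00265, and -2.04 with the mean of probe sets) and S100b (-2.89), with 1 and 4 adjusted over the list alone. Their set reached adjusted p = 0.00353 with the preset and 0.177 with an estimated correlation, with 1 and 4 genes past the threshold without mesenchyme 1.

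Striated muscle genes were higher in mesenchyme for 5 of 9 (8 adjusted over the list alone, median -4.53, or -3.73 without mesenchyme 1, which lay at 2.25 for the list), including Tnnt1, Actc1 (-5.55 ± 0.805, adjusted p = 0.0112), embryonic myosin Myh3 (-5.39) and the myogenic factor Myog (-4.56). Myh3 read 38403 on mesenchyme 1 and 6180 and 3548 on mesenchyme 2 and 3, and 7 of 9 passed without mesenchyme 1. Adjusted p was 1.99e-08 with the preset and 0.201 with an estimated correlation. No macrophage gene passed among 14 (10 at an unadjusted p under 0.05 in limma, 9 adjusted over the list alone), with Csf1r at -2.58 (adjusted p = 0.0835, and 0.0386 with median centring) and Adgre1 at -0.75. The macrophage set reached adjusted p = 4.95e-07 with the preset and 0.295 with an estimated correlation, and 5 passed without mesenchyme 1, which lay at 1.57 for the list.

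Erythroid genes had 0 of 9 past the threshold in limma (0 adjusted over the list alone, 1 at an unadjusted p under 0.05). The embryonic globin Hbb-y read 2301 on mesenchyme 1 and 11189 to 56536 on the others, and Slc4a1, the red cell anion exchanger, read 9469 there and 59 to 750 elsewhere. Nephric duct and ureter genes (0 of 6, 0 adjusted over the list alone, 1 unadjusted) included Ret (-0.50) and Sox9 (-0.25), and their median (-0.15) and mean (0.16) differed in sign. Mesothelial genes (0 of 8, 3 adjusted over the list alone, 5 unadjusted) included Upk1b (4.42, adjusted p = 0.0685) and Krt19 (4.43, adjusted p = 0.0555), which epithelium also uses. With median centring Upk1b (0.0381) and Krt19 (0.023) passed, as did Krt19 with an offset of 64 (0.0472), no normalization (0.0436) or the filter at the 60th percentile (0.0485). Hindgut genes (0 of 5, 0 adjusted over the list alone, 0 unadjusted) included Cdh17, which read 9955 on mesenchyme 1 and at most 142 elsewhere, and Lgals4, 7652 and at most 240. Of 11 hindgut genes on the array, 5 passed the signal filter with all arrays and 2 without mesenchyme 1, so that array partly chose the members tested. These 4 sets had adjusted p of 0.214, 0.915, 0.407 and 0.121, and of 0.478, 0.918, 0.744 and 0.654 with an estimated correlation. Leaving out single arrays moved the medians from -1.62 to 0.11 for the erythroid list, 0.12 to 1.68 for the mesothelial and -3.48 to 0.48 for the hindgut list, and the filter at the 60th percentile gave -2.55 for the erythroid and 3.80 for the mesothelial list. The hindgut set passed without the filter (adjusted p = 0.0382) and without mesenchyme 2 (0.00505) or 3 (0.0172), and the erythroid set without epithelium 5 (0.0372). Without mesenchyme 1 the nephric duct list had 1 gene past the threshold in each direction, the mesothelial list 4 in epithelium and 1 in mesenchyme, and the other 2 lists 0 (2 erythroid and 0 hindgut genes at an unadjusted p under 0.05). None of the 4 sex-linked genes passed (0 adjusted over the list alone, 2 at an unadjusted p under 0.05). Xist nevertheless differed by -3.61 (adjusted p = 0.226 in limma). It read 385 to 592 on the epithelial arrays and 28082, 418 and 17019 on mesenchyme 1, 2 and 3. Y-linked Eif2s3y read 3072 to 5133 on the epithelial arrays and 175 on mesenchyme 3. By these genes sex was unequal between the layers, and the comparison does not adjust for it.

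Across the 28 sets, 16 passed with the preset correlation, 0 with an estimated correlation (6 at an unadjusted p under 0.05) and 9 by fry, which tests whether genes move on balance 1 way and compares no set with other genes. Without mesenchyme 1 the smallest adjusted p with an estimated correlation was 0.0863 (10 lists at an unadjusted p under 0.05).

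Ligands and receptors on opposite sides of the tissue boundary were few. Of 46 pairs tested, 2 had a ligand higher in 1 layer and its receptor higher in the other, Pdgfa (2.63 ± 0.267, adjusted p = 0.00427) in epithelium with Pdgfra (-2.36 ± 0.423, adjusted p = 0.0224) in mesenchyme, and the guidance ligand Sema3c (1.10 ± 0.181, adjusted p = 0.0162) in epithelium with Nrp2 (-3.23 ± 0.502, adjusted p = 0.0139) in mesenchyme. Random re-pairing of the same genes gave 0.849 such pairs on average (one-sided permutation p = 0.199). Without mesenchyme 1 there were 5, with Shh and its co-receptors Boc and Gas1, and mesenchymal Rspo3 with epithelial Lgr4, added, against a re-paired mean of 6.27 (one-sided permutation p = 0.821), so neither count was distinguishable from re-pairing by this test. Pdgfra missed the threshold with median centring (adjusted p = 0.0896) and with the mean of probe sets (0.244), and Sema3c without a variance trend (0.0655). Leaving out epithelium 1 or mesenchyme 2 left 0 pairs, and epithelium 2, epithelium 5 or mesenchyme 3 left 1.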

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

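The setting without mesenchyme 1 and without normalization, and the list and pair values without mesenchyme 1, were tests chosen after the result was seen. Leaving out single arrays gave 27 to 865 genes higher in epithelium, 115 to 1110 higher in mesenchyme, 142 to 1851 changed at least 2-fold and 0 to 5 pairs: in total 142 genes without epithelium 1 (139 shared with the 820), 551 without epithelium 2 (474), 241 without epithelium 5 (232), 1975 without mesenchyme 1 (801), 192 without mesenchyme 2 (190) and 330 without mesenchyme 3 (323). Without mesenchyme 1 and without normalization the counts were 771, 1171 and 1869 genes and 7 pairs. Array quality weights gave 2598, 2511 and 2950 genes and 15 pairs, but the weight estimate stopped before its tolerance was reached, with weights from 0.0501 for mesenchyme 2 to 26.7 for epithelium 1. The test of each gene on its own variance gave 73, 112 and 162 genes and 0 pairs, with 2427 genes at an unadjusted p under 0.05. With the replicate block, limma gave 0, 0 and 0 genes and 0 pairs (1460 genes at an unadjusted p under 0.05) and 18 lists. Only numbers 1 and 2 are shared, which leaves 1 residual degree of freedom. Deviations of same-numbered arrays from their layer's mean correlated at -0.045 and -0.021. The mesenchyme mean includes the outlying mesenchyme 1, so these values cannot show whether a shared number marks the same embryo. Xist read 385 on epithelium 1 and 28082 on mesenchyme 1, so number 1 could mark the same embryo only if RNA of another animal entered mesenchyme 1. For number 2 Xist was low on both arrays (454 and 418), which leaves that number open. Median centring, the mean of probe sets and eBayes without a trend each left 1 pair. Of 28 lists, 0 passed with an estimated correlation (6 at an unadjusted p under 0.05) and 9 by fry. The sign turned in 29 gene and 30 list values. Past the threshold with all arrays were 3 of these: the urothelial differentiation list at -0.0491 without the filter, Tpm2 at 0.014 without cross-matching probe sets and the cell division list, -0.0209 to 0.761 with single arrays left out (lowest without mesenchyme 1). The rest were past the threshold in neither setting, and no cause was tested. Median centring gave Ptch1 0.0871 and Rrm2 0.074, no normalization Krt10 -0.0339 and Wnt ligands -0.13, and offset 64 Krt10 -0.00666. No filter gave FGF 0.0543 and nephric duct 0.192, and the 60th percentile Wnt ligands -0.0402 and Notch 0.145. The mean of probe sets gave Sox9 0.365 and nephric duct 0.162, and all probe sets FGF 0.0198, Eph -0.228, Notch 0.216 and nephric duct 0.257. Array quality weights gave Egr1 -0.0744, Hbb-y -0.886, Pcna -0.147, FGF 0.00797, retinoic acid 0.0741 and hindgut 0.541. The replicate block gave Krt10 -1.12, Ptch1 0.0718, Ret 0.00503, Sox9 0.406, retinoic acid 0.0476, Notch 0.024, nephric duct 0.267 and mesothelium -0.0526. Without mesenchyme 1 and without normalization, Hbb-y was at -0.666, Lgals4 0.174, Rxrb -0.0429, posterior Hox -0.343, Eph -0.112 and hindgut 0.511. With single arrays left out, values ran from -0.105 to 1.15 for Egr1, -1.21 to 1.10 for Hbb-y, -0.997 to 1.80 for Krt10, -2.78 to 0.134 for Lgals4, -0.0821 to 0.152 for Pcna, -0.0648 to 0.512 for Rxrb and -0.897 to 0.279 for Sox9. For lists they ran from -0.131 to 0.602 for Wnt ligands, -0.261 to 1.34 for posterior Hox, -0.0114 to 0.438 for Eph, -3.48 to 0.483 for hindgut, -1.62 to 0.105 for erythroid and -0.584 to 0.279 for nephric duct. Of the other gene and setting combinations 1759 kept direction and side of the threshold, 55 newly passed (19 with array quality weights) and 365 no longer passed, and for lists 537, 15 and 34. Pair counts were not made for all probe sets, nor list tests for the test of each gene on its own variance. Without detection calls, the signal over background that limits dim genes is unknown.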

Other observations

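All tests in this part but the splits of the arrays were chosen after the result was seen; for the organ markers, that was after the array was seen to differ and before their own values were. Gene families were picked by symbol, and 21 of their 69 genes past the threshold also stand in the lists above. Of 19 families, each tested for excess in both directions with Fisher's exact test against all 13717 tested genes, semaphorins, secreted or membrane-bound guidance proteins, were in excess on both sides. Sema3e (3.94 ± 0.420), Sema3d (2.06) and Sema3c (1.10) were higher in epithelium (3 of 19, adjusted p = 0.0237), and Sema3g (-2.94), Sema4f (-2.62), Sema6d (-2.62), Sema5a (-1.89) and Sema7a (-1.68) in mesenchyme (5 of 19, adjusted p = 0.0133). The ADAMTS matrix proteases had 4 of 13 higher in mesenchyme, Adamts4 (-3.20), Adamts3 (-2.66), Adamts12 (-2.53) and Adamts9 (-2.38), adjusted p = 0.0133. Cadherins had 4 of 15 there, Cdh5, Cdh2 (-4.02 ± 0.428), Cdh11 (-2.83) and Cdh6 (-2.69), adjusted p = 0.0158. By the same test, claudins (adjusted p = 0.0132), grainyhead genes (0.0133) and Irx genes (0.0172) were in excess in epithelium. Synaptotagmin and synaptic genes (0.0158) and Tbx genes (0.017) were in excess in mesenchyme, and the other families passed in neither direction. Genes of a family are not independent, so these p-values are too small. Without mesenchyme 1, the counts higher in epithelium and in mesenchyme were 3 and 6 of 19 semaphorins, 1 and 7 of 13 ADAMTS genes and 3 and 5 of 14 cadherins, so that the cadherins then split between the layers.

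Without mesenchyme 1, the largest differences in epithelium were the desmosomal Pkp1 (7.35 ± 0.423, adjusted p = 0.000607), the basal keratin Krt15 (7.24), Elf5 (6.98), Cldn23 (6.60), Clca1 (6.49), E-cadherin Cdh1 (6.46) and the splicing regulator Esrp2 (6.28). With all 6 arrays Pkp1 had 4.48 and adjusted p = 0.294, and Cdh1 4.57 and adjusted p = 0.18 in limma. In mesenchyme Rgs4 (-8.27), Aplnr (-8.05) and Prph (-7.61) led, and the sodium channel subunit Scn3b (-6.05) and Tbx4 (-5.97) joined.

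The array labelled mesenchyme 1 held 610 genes over 4-fold above the highest of the other 5 arrays, where no other array held more than 3, and 284 genes over 4-fold below the lowest, and epithelium left on the mesenchyme, which would give values between the layers, cannot be the whole cause of those 610 genes, though junction genes and keratins were also high there. Degradation or a short amplification beyond that of the other arrays is argued against by 3' to 5' signal ratios. The ratio of Gapdh was 23.12 on mesenchyme 1 and 15.54 to 32.35 on the others, and that of beta-actin 7.31 and 8.64 to 11.33. Signal was far higher at the 3' end on every array, so these ratios only compare arrays with each other. A single male embryo is argued against by Xist at 47.5 times its highest level on the 4 arrays with low Xist. A single female embryo stays open with 1 such array, mesenchyme 3, to compare, since Eif2s3y and Kdm5d were 8.81 and 4.06 times their level there but Uty 1.03, and relative to the median of the 4 arrays with high Y-linked signal these stood at 0.384, 0.259 and 0.154. RNA from organs outside the lower urinary tract is a candidate source, since 55.1% of 49 organ markers (27, with 0 on each other array) lay over 4-fold above: 8 of 8 for liver (Alb 58365, Ttr 59268), 5 of 6 for heart, 3 of 4 for lung, 2 of 2 for eye, 3 of 8 for brain, 2 of 4 each for pancreas, skin and kidney, and 0 of 6 for testis and 0 of 3 for lymphoid cells (of the 49, 0 stand in the lists above and 14 exceed the filter level on the other arrays). A small share of tissue added to the labelled layer would leave that layer's genes near their level. It cannot be the whole cause of the 284 genes over 4-fold below the lowest, where no other array held more than 102. Whether this may be a large share of tissue carried in, RNA of several animals, an older stage or another sample under this label stays open. The labels give this array the same layer and stage as mesenchyme 2 and 3. Hoxd13 (504) and Isl1 (978) lay far below the other mesenchyme arrays.

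Epithelial genes were higher on mesenchyme 2 than on mesenchyme 3. Of 69 genes of the epithelial lists, 63 were over 4-fold higher in epithelium than on mesenchyme 3, a choice that favours higher values on mesenchyme 2. Of these 63, 61 (96.8%) were higher on mesenchyme 2. The median difference over the 63 was 3.53% of the epithelial level (quartiles 2.17% and 5.8%). Single genes spread more widely, from 0.454% for Zfp750 to 11.6% for Krt18 and 43.2% for Krt20, with Foxa1 at 5.85%, Ovol2 (-5.2%) and Irx5 (-1.84%) the other way, and Shh, outside the lists, at 12.2%. A small share of epithelium left on mesenchyme 2 may account for the shift shared by most of these genes, but a single share does not give the spread between them. Mesenchyme 2 has Y-linked transcripts (Eif2s3y 4579) and mesenchyme 3 has Xist (17019), so a difference between male and female embryos stays open, as untested with 1 array of each.

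The 6 arrays make 10 splits into 3 and 3, of which 1, the real split, gave as many as 820 genes in limma, and the highest of the others gave 0. These splits are too few for a share under 0.05.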
